A study of Mus musculus with 9 samples.

How the data were processed

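Gene expression was measured in 3 layers of the neonatal mouse bladder, the detrusor (the smooth muscle coat), the stroma and the urothelium (the lining epithelium), each captured from frozen sections by laser capture microscopy, per the labels. The mice were FVB/N animals carrying an EGFP transgene for smooth muscle gamma actin (Actg2), per the labels. Total RNA from each captured sample was amplified in more than 1 round, labelled with biotin and hybridised to an Affymetrix MOE430 array, 1 array per sample and unpooled, per the labels' protocols. The table held 9 arrays, 3 per layer, of which 4 came from postnatal day 1 and 5 from day 2, with both days present in every layer. Detrusor had more arrays from day 1 than from day 2, and stroma and urothelium the reverse. Samples were put into layers by the tissue source given in the labels, and all 9 columns were used. The labels do not tie captured samples to animals and do not give the number of animals, so samples of different layers may share an animal, and the p-values then measure only the spread between these samples, which may be technical and may be too small if arrays of 1 layer share an animal.

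The deposited values are linear probe set intensities made by the authors with GCOS, the Affymetrix array software, per the submitters' processing notes. Its version, algorithm and scaling target are not given in the sources used here. The mean after removing the lowest and highest 2% of probe sets was between 1499 and 1500 on every array, so each array had been scaled to 1 level before deposit, and this scaling was kept. The table carries no detection calls or background values, so a low value cannot be called absent. The median probe set signal of an array ranged from 133.3 to 388.5 intensity units. For arrays, the number of samples limits the precision, and the median standard error of a difference between layers was 0.45 on the log2 scale.

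Of 45101 probe sets, 64 were array controls, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were not named there. Symbols were looked up by gene identifier in a gene table of assembly GRCm38.p6, used for names only. The lookup matched 34754 probe sets and changed 0 symbols. Values were taken as log2(intensity + 39.31), the pseudocount being the 20th percentile of all values, so fold changes are on that scale and understate the change of low genes. Probe sets at or above their array's median on at least 3 of the 9 arrays were kept (22207 with 1 symbol), and the probe set with the highest mean stood for its gene, which left 13064 genes. For 5620 genes more than 1 probe set passed. Among 252 pairs of a named gene and a comparison, 109 had several probe sets, 9 had one of the opposite sign and 0 had an opposite one past the threshold.

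Layers were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) in 1 fit over all 9 arrays with layer as the only term. Postnatal day was tested with layer as a covariate. P-values were adjusted by Benjamini-Hochberg and genes with an adjusted p under 0.05 were called. A gene was called enriched in a layer when it was called against both others and was at least 1 log2 unit higher in each. Gene lists, 19 in all, were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over 57 tests, and again with an estimated correlation, and with fry. Members called are counted over all genes tested and also adjusted over the list alone. The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Actg2, the 6 genes with the largest difference in each direction among called genes whose arrays did not overlap, for each list the 4 members with the smallest adjusted p and up to 2 called members going against the list, the 5 largest day differences in each direction and the 6 largest enriched genes per layer. Genes named outside it are said to be so. The lists hold textbook markers and none was chosen on these samples.

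The tests were checked on simulated values with the real genes' means and spread and no correlation between genes. In the detrusor and stroma comparison, 13064 genes with 50 changed at each size, 4% of changes of 1 log2 unit, 32% of 2, 82% of 3 and 86% of 4 were recovered. For urothelium and stroma the shares were 2%, 48%, 72% and 76%, and for urothelium and detrusor 2%, 50%, 80% and 90%. Unchanged genes were called at 0.0233%, 0.0389% and 0.0544% in the 3 comparisons. The day test recovered 90% of changes of 4 log2 units. The enriched rule recovered 78.3% of genes raised by 4 in urothelium, and so did the F-test. An unadjusted p under 0.05 went to 2.5% of unchanged random sets with camera, 0.5% with an estimated correlation and 4.5% with fry. The test of layer by day recovered 0% of changes of 4 log2 units and 80% of changes of 8.

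The alternatives tried were quantile normalization, median centring, 2 other pseudocounts (8.13, the 5th percentile, and 232.9, the median), no filter and a filter at the 75th percentile, the mean over a gene's probe sets, every probe set on its own, no variance trend, array weights, postnatal day as a covariate, only the 6 arrays of the layers compared, and leaving out each array in turn. Leaving out several arrays together was added after the values were seen. After results had been seen, the record of named genes under these alternatives was limited to the called pairs of gene and comparison plus Actg2. Probe sets with no or several symbols entered no comparison of genes. No genome coordinates are given, since the sources used here name no build for these values.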

Results

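Transcript levels were measured on 9 arrays of laser-captured bladder tissue from newborn mice, with 3 arrays each for detrusor, stroma and urothelium. The mice carried a smooth muscle gamma actin EGFP transgene, and the comparisons ask which transcripts set each bladder layer apart around birth. After the filter on dim probe sets, 13064 genes were tested on a log2 scale. The first principal component held 43.7% of the variance and separated detrusor, between -92.26 and -76.28, from urothelium, between 50.33 and 98.56. Stroma lay between them, at -4.13, -3.75 and 37.17. The median SD of a gene within a layer was 0.39 log2 units in detrusor, 0.56 in stroma and 0.42 in urothelium (n = 3 each). The closest array to stroma 3 by Pearson's r across genes was urothelium 1 (0.90), and the closest to stroma 2 was detrusor 1 (0.83), whereas every detrusor and urothelium array was closest to one of its own layer. Genes are not independent replicates, so these correlations only describe the arrays. The 3' to 5' signal ratio of the Actb control probe sets, a measure of RNA degradation and of amplification from the 3' end, ranged from 2.27 to 7.49 in detrusor, from 5 to 24.67 in stroma and from 5.32 to 8.49 in urothelium. That of Gapdh overlapped between layers, from 15.9 to 34.7 in detrusor, from 15.3 to 31.8 in stroma and from 19.1 to 23.4 in urothelium.

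**Figure D1:**
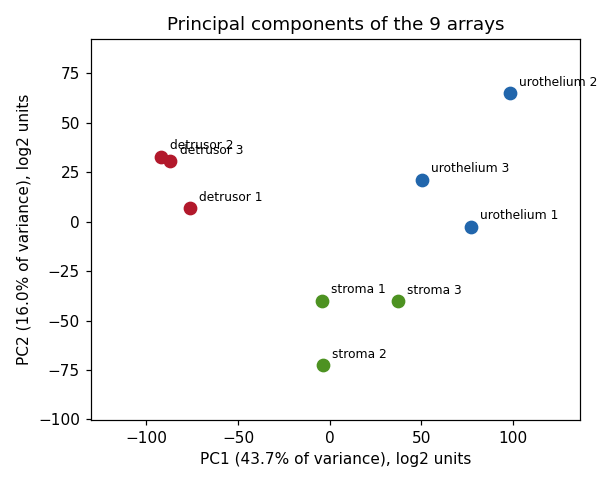
Principal components 1 and 2 of the 9 arrays from the log2 levels of all genes tested, 1 point per array, coloured by layer. Detrusor lies at the left, urothelium at the right, and stroma 3 (37.17 on component 1) nearer to urothelium than stroma 1 and 2 do.

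Actg2, the smooth muscle gamma actin gene whose transgene the mice carried, had log2 levels of 16.1, 16.7 and 16.3 in the detrusor arrays. Its levels were 15.3, 12.1 and 15.1 in stroma and 10.9, 9.64 and 16.3 in urothelium, so that urothelium 3 reached the detrusor level. Its difference did not pass the limma test for detrusor against stroma (log2 2.22 ± 1.42, SE, adjusted p = 0.381), for urothelium against stroma (log2 -1.86 ± 1.42, adjusted p = 0.518) or for urothelium against detrusor (log2 -4.08 ± 1.42, adjusted p = 0.0762). Between urothelium and detrusor Actg2 did pass with array weights (-4.11, adjusted p = 0.0177), without urothelium 3 (-6.09, adjusted p = 0.0013) and without stroma 3 and urothelium 3 (-6.09 ± 0.81, adjusted p = 0.00149). It also passed with stroma 1 left out as well (adjusted p = 8.469e-05), and the other alternatives gave adjusted p from 0.0515 to 0.25. Between detrusor and stroma the alternatives gave adjusted p from 0.108 to 0.673, apart from the setting without stroma 1, stroma 3 and urothelium 3 (4.33, adjusted p = 0.00374). That setting leaves 1 stroma array, the one with the lowest Actg2, with a spread taken from the other layers, so it does not bear on this gene. The sets of several arrays were chosen for leaving out after levels were seen. 2 further markers, picked after their levels were seen, show which arrays carry transcripts of another layer. Myh11, smooth muscle myosin heavy chain, had a log2 level of 15.7 in urothelium 3 against 9.75 and 8.03 in urothelium 1 and 2. Upk1b, a uroplakin of the urothelial plaque, stood at 16.0 in stroma 3, 12.5 in stroma 1 and 10.3 in stroma 2, with 15.7, 16.1 and 15.9 in urothelium.

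Several muscle genes stood out in detrusor against stroma. On the scale used, the differences of Myh8, the perinatal myosin heavy chain (94.1-fold, log2 6.56 ± 1.12, SE, n = 3 per layer), Trdn, triadin of the calcium release complex (93.9-fold, log2 6.55 ± 0.53), and P2rx1, the ATP-gated receptor of detrusor contraction (74.9-fold, log2 6.23 ± 1.42), came first. The stroma levels of Trdn, 5.38 to 5.64, and Myh8, 5.48 to 6.98, lie near the bottom of the scale, so their differences and order depend on the pseudocount. At its 5th percentile and median settings the differences were 8.30 and 4.21 for Trdn and 7.62 and 4.66 for Myh8. Rims1, Tenm2 and Ckm, muscle creatine kinase, followed at 58.8-fold, 52.6-fold and 49.3-fold. In the other direction, Adamdec1 (log2 -6.30 ± 0.67), Gsdmc2 (-6.17 ± 1.15), the epithelial adhesion gene Epcam (-6.03 ± 0.71), Krt15 (-5.98 ± 1.09), Smim22 (-5.82 ± 0.66) and Ripk4 (-5.72 ± 0.58) were lower in detrusor. Gsdmc2 was not called without stroma 3 and urothelium 3 (-5.23 ± 1.23, adjusted p = 0.0568). Each gene named here as lower in detrusor was also at least 3 log2 units higher in urothelium 1 and 2 than in any detrusor array. Stroma 3, and less so stroma 1, carried transcripts of such genes, so these differences may not mark stroma itself. In all, limma called 763 genes, 408 higher and 355 lower in detrusor. Of all genes tested, 27.1% had arrays that did not overlap between these layers, against 10% by chance.

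By list, 10 of 26 smooth muscle contractile genes were higher in detrusor than in stroma and 0 lower, or 20 when adjusted over the list alone. Hspb6 (log2 4.48 ± 0.51), Smtn (4.22 ± 0.67), Ppp1r12b (3.54 ± 0.54) and Pcp4 (5.46 ± 1.03) led the list, whose median difference was 3.40 (camera adjusted p = 2.605e-14, adjusted p = 0.397 with an estimated correlation). Of the excitability and receptor genes, 3 of 13 were higher, or 8 when adjusted over the list alone, among them Pln, the phospholamban that restrains the calcium pump (4.77 ± 0.67), P2rx1 and the large-conductance potassium channel gene Kcnma1 (1.86 ± 0.43). For the excitability genes, camera gave adjusted p = 2.42e-06, and adjusted p = 0.381 with an estimated correlation. Of the skeletal muscle genes, 3 of 9 were higher, namely Ckm, Myh8 and the fast troponin Tnnt3 (5.15 ± 1.04), also 3 over the list alone. For the skeletal muscle genes, camera gave adjusted p = 0.0181, and adjusted p = 0.496 with an estimated correlation. The median of this list stood at 13.3 in detrusor 1, 8.29 in detrusor 2 and 8.60 in detrusor 3, against 8.39 to 8.79 in stroma. Without stroma 3 and urothelium 3, 19 of the 26 contractile genes were higher and Kcnma1 was not called (1.85 ± 0.52, adjusted p = 0.0898). With quantile normalization 5 excitability genes were called and with median centring 6.

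**Figure D2:**
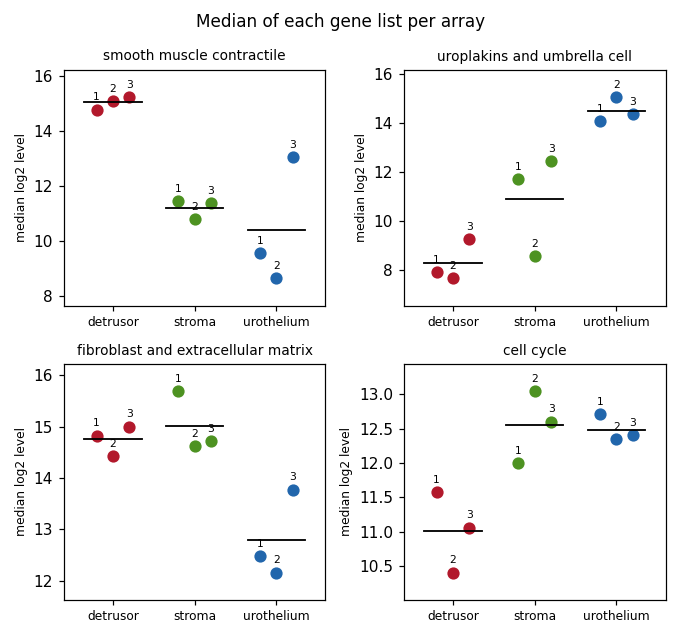
Median log2 level of 4 gene lists on each array, 1 point per array with its replicate number and a line at the mean of the 3 arrays of a layer. The smooth muscle median of urothelium 3 (13.0) stands above urothelium 1 and 2 (9.56 and 8.63), and the uroplakin medians of stroma 1 and 3 (11.7 and 12.4) stand above stroma 2 (8.55).

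Some epithelial and cell cycle genes were lower in detrusor than in stroma. Of the epithelial keratin and junction genes, 11 of 25 fell, or 16 over the list alone, with Epcam, Esrp1 (log2 -5.09 ± 0.60), Ocln (-5.33 ± 0.71) and Dsp (-4.61 ± 0.78) first. For the keratin and junction genes, camera gave adjusted p = 5.248e-09, and adjusted p = 0.381 with an estimated correlation. Of the epithelial transcription factors, 6 of 14 fell, or 9 over the list alone, including Grhl2 (-3.46 ± 0.42), Ehf (-5.69 ± 0.75), Foxq1 (-5.13 ± 0.94) and Gata3 (-4.23 ± 0.95). For the epithelial transcription factors, camera gave adjusted p = 7.118e-07, and adjusted p = 0.397 with an estimated correlation. Of the uroplakin and umbrella cell genes, 2 of 11 fell, Krt20 (-2.86 ± 0.70) and Sprr1a (-4.87 ± 1.26), or 9 over the list alone. For the uroplakin genes, camera gave adjusted p = 7.705e-05, and adjusted p = 0.397 with an estimated correlation. These epithelial lists were raised in stroma 1 and stroma 3 relative to stroma 2, with uroplakin list medians of 11.7, 12.4 and 8.55. Of the cell cycle genes, 10 of 24 fell in detrusor, or 22 over the list alone, led by Cdc20 (-2.06 ± 0.26), the replication helicase gene Mcm5 (-1.87 ± 0.31), Cdk1 (-1.71 ± 0.32) and Mcm4 (-1.44 ± 0.28). For the cell cycle genes, camera gave adjusted p = 3.079e-11, and adjusted p = 0.381 with an estimated correlation. With arrays centred on their medians, 2 of the 24 cell cycle genes were called, with a list median of -1.03 against -1.45 as deposited. Without stroma 3 and urothelium 3, called as lower were 0 of 11 uroplakin genes (Krt20 -2.32 ± 0.77, adjusted p = 0.137, Sprr1a -3.53 ± 1.19, adjusted p = 0.143), 3 of 14 epithelial transcription factors (Gata3 -2.93 ± 0.67, adjusted p = 0.0512), 8 of 25 keratin and junction genes and 4 of 24 cell cycle genes. The list medians were then -2.06, -1.59, -2.27 and -1.37, against -3.06, -2.41, -2.99 and -1.45 with all arrays.

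Signalling genes differed in both directions between detrusor and stroma. Of the Hedgehog and BMP genes, 6 of 20 fell, also 6 over the list alone, and 2 rose, or 3 over the list alone. Ptch1, the Hedgehog receptor and a target of the pathway (log2 -2.15 ± 0.26), Bmp2 (-3.60 ± 0.44) and Bmp7 (-2.64 ± 0.42) were lower in detrusor, and Bmpr1a (1.26 ± 0.23) and Cdon (1.90 ± 0.47) were higher. Camera did not call the Hedgehog and BMP list (adjusted p = 0.168), whereas fry did (adjusted p = 0.04265). Conversely, camera called some lists here that fry did not. By fry, adjusted p was 0.0629 for smooth muscle, 0.0769 for uroplakin, 0.0522 for Wnt, 0.174 for skeletal muscle and 0.293 for endothelial genes. Of the Wnt genes, 3 of 20 fell, or 5 over the list alone, namely Lef1 (-3.08 ± 0.48), Wnt4 (-4.62 ± 0.91) and Wnt7b (-1.70 ± 0.43). For the Wnt genes, camera gave adjusted p = 0.034, and adjusted p = 0.397 with an estimated correlation. Aldh1a2, which makes retinoic acid, was the 1 retinoid gene of 11 that fell (-2.73 ± 0.42), also 1 over the list alone. The retinoid list was not called by camera (adjusted p = 0.0554) but was by fry (adjusted p = 0.04165). Among 23 mesenchymal transcription factors 2 rose, Hoxd13 (3.12 ± 0.61) and Meis1 (1.54 ± 0.36), also 2 over the list alone. That list was not called (adjusted p = 0.545), and its median of -0.14 and mean of 0.21 differed in sign. Of the fibroblast and matrix genes, 1 of 27 fell, Mmp2 (-1.37 ± 0.30), also 1 over the list alone (list adjusted p = 0.646), so most matrix genes were not told apart between these layers. The heat shock genes Hspa1b (2.46 ± 0.27) and Hspa1a (1.98 ± 0.46) rose and the immediate-early gene Ier2 (-1.23 ± 0.30) fell in detrusor, out of 15 stress genes, with 2 and 6 over the list alone (list adjusted p = 0.387). Without stroma 3 and urothelium 3, 1 Wnt gene was called and the Wnt list was not (median -0.53 against -0.59 with all arrays, adjusted p = 0.0738). The calls of Wnt4 (-4.08 ± 1.05), Wnt7b (-1.41 ± 0.45), Cdon (1.47 ± 0.47), Meis1 (1.32 ± 0.36), Hspa1a (2.10 ± 0.52) and Ier2 (-1.20 ± 0.36) were lost, each with its direction kept. Bmp2 and Wnt4 were also at least 3 log2 units higher in urothelium 1 and 2 than in any detrusor array. Stroma 3, and less so stroma 1, carried transcripts of such genes, so the Bmp2 and Wnt4 differences may not come from stroma itself. Bmp7, Wnt7b, Lef1 and Aldh1a2 were called higher in urothelium than in detrusor too, by less, so urothelial transcripts may add to their differences. Of these, Bmp7 (-2.41 ± 0.50), Lef1 (-3.03 ± 0.59) and Aldh1a2 (-2.60 ± 0.51) were still called without stroma 3 and urothelium 3.

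Lists of other cell types had 0 called members between detrusor and stroma. The 14 endothelial genes had a median of -1.11, and camera gave adjusted p = 0.0276, and adjusted p = 0.702 with an estimated correlation. The 15 macrophage and leukocyte genes had a median of -0.77 (adjusted p = 0.077), the 10 neural and glial genes -0.53 (adjusted p = 0.646), the 7 pericyte genes 0.45 (adjusted p = 0.311), the 5 mesothelial genes -1.21 (adjusted p = 0.101, with 2 lower over the list alone) and the 2 erythroid genes -0.99 (adjusted p = 0.646). Centring the arrays on their medians moved the median difference of all genes by 0.41 log2 units and gave 588 higher and 144 lower genes instead of 408 and 355. The count was 369 without detrusor 1, 190 without detrusor 2, 105 without detrusor 3, 403 without stroma 3, and 428 (302 higher and 126 lower) without stroma 3 and urothelium 3 together. In that setting the endothelial list was not called (median -1.13, adjusted p = 0.0555).

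Between urothelium and stroma few genes passed. The largest differences among those lower in urothelium were those of Stmn3 (log2 -4.12 ± 0.62, SE, n = 3 per layer), Creb5 (-3.91 ± 0.62), the mesenchymal ligand gene Wnt2 (-3.82 ± 0.58), the chemokine gene Cxcl12 (-3.59 ± 0.50), Pi15 (-3.26 ± 0.45) and Htra3 (-3.25 ± 0.52). Higher in urothelium were the tight junction gene Cldn8 (18.4-fold, log2 4.20 ± 0.64), Mpzl3 (log2 3.46 ± 0.55), Sytl2 (7.01-fold), Gstm4 (6.56-fold), Dcaf12l1 (5.94-fold) and Hsdl2 (5.11-fold). Limma called 30 genes, 8 higher and 22 lower in urothelium, and 2481 genes had an unadjusted p under 0.05. The arrays of 23.1% of all genes did not overlap between these layers, against 10% by chance.

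Of the fibroblast and matrix genes, 3 of 27 were lower in urothelium than in stroma, the proteoglycan gene Dcn (log2 -3.20 ± 0.45), Vim (-2.46 ± 0.34) and Col5a1 (-2.54 ± 0.42), and all 27 were when adjusted over the list alone. For the fibroblast and matrix genes, with a median of -1.90, camera gave adjusted p = 2.034e-15, and adjusted p = 0.381 with an estimated correlation. Of the mesenchymal transcription factors, 2 of 23 fell, Twist2 (-2.68 ± 0.42) and Tcf21 (-2.89 ± 0.47), or 10 over the list alone. For the mesenchymal transcription factors, camera gave adjusted p = 1.46e-05, and adjusted p = 0.397 with an estimated correlation. Wnt2 was the 1 Wnt gene of 20 that fell, with 1 rising and 2 falling over the list alone (list adjusted p = 0.271). None of the 11 uroplakin and umbrella cell genes was called over all genes, although 10 were over the list alone. For the uroplakin genes, with a median of 2.97, camera gave adjusted p = 1.617e-08, and adjusted p = 0.381 with an estimated correlation. Likewise 0 of 25 keratin and junction genes were called and 13 were over the list alone. For the keratin and junction genes, with a median of 2.13, camera gave adjusted p = 1.275e-11, and adjusted p = 0.381 with an estimated correlation. For the 14 epithelial transcription factors the numbers were 0 and 9. For the epithelial transcription factors, with a median of 2.37, camera gave adjusted p = 3.183e-08, and adjusted p = 0.381 with an estimated correlation. With median centring 2 uroplakin genes, 4 keratin and junction genes, 2 epithelial transcription factors and 5 matrix genes were called, and with quantile normalization 0, 0, 0 and 8. The same arrays carried other layers' transcripts here, with a uroplakin list median of 12.4 in stroma 3 against 14.1 to 15.1 in urothelium.

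No other list had a member called between urothelium and stroma. Camera called the 14 endothelial genes (median -1.62, adjusted p = 1.136e-05, and adjusted p = 0.411 with an estimated correlation), 7 of them lower over the list alone. The 15 macrophage genes were called too (-1.76, adjusted p = 0.000166, and adjusted p = 0.452 with an estimated correlation), 6 lower over the list alone. So were the 7 pericyte genes (-1.57, adjusted p = 0.0449, and adjusted p = 0.509 with an estimated correlation), with 1 higher and 4 lower. The 20 Hedgehog and BMP genes were the last (-0.69, adjusted p = 0.046, and adjusted p = 0.397 with an estimated correlation), with 2 higher and 5 lower. The smooth muscle (-0.83, adjusted p = 0.311), excitability (-0.59, adjusted p = 0.361), retinoid (0.08, adjusted p = 0.585), neural (-0.62, adjusted p = 0.646, with 2 higher and 1 lower over the list alone), mesothelial (-1.07, adjusted p = 0.73), skeletal muscle (-0.20, adjusted p = 0.743), erythroid (-0.47, adjusted p = 0.836), cell cycle (-0.19, adjusted p = 0.545) and stress (0.22, adjusted p = 0.545, with 1 higher and 2 lower over the list alone) lists were not called. The retinoid list had a mean of -0.10, opposite in sign to its median. Median centring moved the median difference of all genes by 0.42 and gave 192 higher and 31 lower genes instead of 8 and 22. Quantile normalization gave 42 higher and 51 lower, and the test without the variance trend called 0 genes. The count was 0 without detrusor 1, stroma 1 or urothelium 2, 2 without detrusor 3, 1 without urothelium 1, 50 without stroma 2, 528 without stroma 3, 102 without urothelium 3, and 440 (217 higher and 223 lower) without stroma 3 and urothelium 3 together. In that last setting the Hedgehog and BMP list was not called (median -0.86, adjusted p = 0.117) and the excitability list was (adjusted p = 0.0445). The smooth muscle list was called there too, with a median of -1.90. For it camera gave adjusted p = 1.813e-09, and adjusted p = 0.357 with an estimated correlation. Urothelium 3, left out in this setting, carried smooth muscle transcripts.

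Urothelium and detrusor were the most distinct pair by number of genes called. Shh, the epithelial Hedgehog ligand, came first on the scale used (752-fold higher in urothelium, log2 9.56 ± 1.11, SE, n = 3 per layer). Its detrusor levels of 5.52 to 6.40 lie near the bottom of the scale, and its difference was 10.8 and 7.44 with the pseudocount at the 5th percentile and the median. Next were Gsdmc2 (456-fold), Krt15 (401-fold, log2 8.65 ± 1.09), the transcription factor gene Foxa1 (362-fold, log2 8.50 ± 1.14), Cldn8 (298-fold, log2 8.22 ± 0.64) and Ripk4 (273-fold). Lower in urothelium were the fast skeletal troponin gene Tnnc2 (log2 -7.22 ± 0.95), Trdn (-6.62 ± 0.53), P2rx1 (-6.57 ± 1.42), the actin gene Acta1 (-6.45 ± 1.78), Tnnt3 (-6.26 ± 1.04) and Tnnt2 (-6.11 ± 1.44). Tnnc2 (5.78 and 5.64), Trdn (5.38 and 5.39) and Tnnt3 (5.85 and 5.43) lay near the bottom of the scale in urothelium 1 and 2. Their differences and order thus depend on the pseudocount. Urothelium 3 stood higher for Tnnc2 (10.2), Tnnt3 (10.3) and Acta1 (14.8, against 8.21 and 5.98 in urothelium 1 and 2). Limma called 2145 genes, 1094 higher and 1051 lower in urothelium. The arrays of 39.3% of all genes did not overlap, against 10% by chance.

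Every one of the 11 uroplakin and umbrella cell genes rose in urothelium against detrusor, also 11 over the list alone, among them Krt20 (log2 6.14 ± 0.70), Snx31 (6.61 ± 1.00), Upk3b (6.26 ± 0.95) and Mal (5.95 ± 0.94). For the uroplakin genes, with a median of 6.14, camera gave adjusted p = 3.979e-10, and adjusted p = 0.381 with an estimated correlation. Of the keratin and junction genes, 19 of 25 rose, or 22 over the list alone, led by Esrp1 (7.12 ± 0.60), Epcam (7.80 ± 0.71), Cldn7 (6.22 ± 0.61) and Ocln (6.72 ± 0.71). For the keratin and junction genes, camera gave adjusted p = 4.69e-16, and adjusted p = 0.381 with an estimated correlation. Of the epithelial transcription factors, 12 of 14 rose, or 13 over the list alone, with Ehf at 8.02 ± 0.75, Foxq1 at 7.84 ± 0.94 and the grainyhead-like genes Grhl2 and Grhl3 at 4.74 ± 0.42 and 4.90 ± 0.58. For the epithelial transcription factors, camera gave adjusted p = 9.694e-12, and adjusted p = 0.381 with an estimated correlation. Of the cell cycle genes, 12 of 24 rose, or 15 over the list alone, including Mcm5 (1.78 ± 0.31), Cdc20 (1.49 ± 0.26), Bub1b (2.01 ± 0.39) and the proliferation marker Mki67 (1.33 ± 0.29). For the cell cycle genes, camera gave adjusted p = 1.798e-08, and adjusted p = 0.381 with an estimated correlation. With median centring 7 of the 24 were called, with a list median of 1.25 against 1.24 as deposited. Without stroma 3 and urothelium 3, 4 of the 24 cell cycle genes were called, with a list median of 1.21 against 1.24 with all arrays, and Mki67 was not (1.15 ± 0.34, adjusted p = 0.052).

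Contractile genes fell in urothelium against detrusor, 20 of 26 over all genes and 22 over the list alone, and the first of them were Hspb6 (log2 -4.35 ± 0.51), Smtn (-4.19 ± 0.67), Ppp1r12b (-3.17 ± 0.54) and Pcp4 (-5.65 ± 1.03). For the contractile genes, with a median of -4.16, camera gave adjusted p = 3.559e-12, and adjusted p = 0.397 with an estimated correlation. Of the excitability genes, 7 of 13 fell, or 10 over the list alone, among them Pln (-5.05 ± 0.67), Pde5a (-1.84 ± 0.32) and Prkg1 (-2.33 ± 0.47), the last 2 parts of the cyclic GMP pathway. For the excitability genes, camera gave adjusted p = 1.136e-05, and adjusted p = 0.381 with an estimated correlation. Of the skeletal muscle genes, 4 of 9 fell, also 4 over the list alone, namely Ckm (-5.59 ± 0.82), Tnnt3, Myh8 (-5.51 ± 1.12) and Acta1. For the skeletal muscle genes, camera gave adjusted p = 0.0299, and adjusted p = 0.509 with an estimated correlation. Urothelium 3 carried smooth muscle transcripts, with a list median of 13.0 against 9.56 and 8.63 in urothelium 1 and 2 and 14.8 to 15.2 in detrusor. Matrix genes also fell, 16 of 27, or 22 over the list alone, with Lum (-2.80 ± 0.47), Vim (-2.0025 ± 0.34), Dpt (-3.17 ± 0.56) and Postn (-3.05 ± 0.57) first. For the fibroblast and matrix genes, camera gave adjusted p = 1.083e-09, and adjusted p = 0.397 with an estimated correlation. Of the mesenchymal transcription factors, 9 of 23 fell, or 12 over the list alone, including Prrx1 (-4.48 ± 0.73), Hoxd13 (-3.59 ± 0.61), Tbx18 (-4.29 ± 0.86) and Zeb2 (-2.13 ± 0.43). For the mesenchymal transcription factors, camera gave adjusted p = 8.51e-05, and adjusted p = 0.397 with an estimated correlation.

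**Figure D3:**
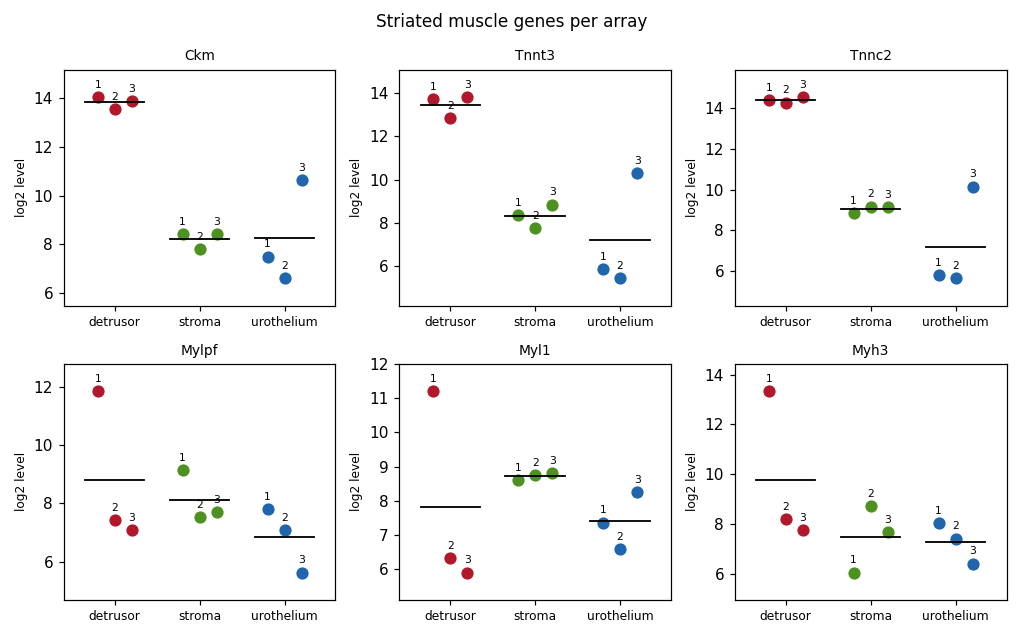
Log2 levels of 6 striated muscle genes on each array, 1 point per array with its replicate number and a line at the mean of the 3 arrays of a layer. Ckm, Tnnt3 and Tnnc2 were high on all 3 detrusor arrays, whereas Mylpf, Myl1 and Myh3 were high on detrusor 1 (11.9, 11.2 and 13.3) and not on detrusor 2 and 3.

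Signalling lists split between urothelium and detrusor. Of the Hedgehog and BMP genes, 6 of 20 rose and 5 fell, or 6 and 7 over the list alone, with Shh, Bmp2 (log2 4.95 ± 0.44) and Bmp7 (2.79 ± 0.42) higher and the receptor gene Bmpr1a (-1.33 ± 0.23) lower in urothelium. That list was not called, and its median of -0.42 and mean of 0.36 differed in sign (adjusted p = 0.646). Of the Wnt genes, 5 of 20 rose and 3 fell, or 6 and 3 over the list alone, with Wnt4 (5.68 ± 0.91), Wnt7b (2.31 ± 0.43), Fzd6 (1.88 ± 0.40) and Lef1 (2.22 ± 0.48) among those that rose (list median -0.06, mean 0.33, adjusted p = 0.545). In the retinoid list, 3 of 11 genes rose, also 3 over the list alone, namely Aldh1a2 (2.29 ± 0.42), the receptor gene Rxra (1.79 ± 0.34) and Dhrs3 (1.42 ± 0.34). For the retinoid genes, camera gave adjusted p = 0.034, and adjusted p = 0.383 with an estimated correlation. Among 15 stress genes, Ier2 (1.13 ± 0.30), Junb (1.48 ± 0.43) and Fosb (2.9995 ± 0.88) rose and Hspa1b (-1.14 ± 0.27) fell, with 6 and 3 over the list alone (list adjusted p = 0.311). Without stroma 3 and urothelium 3 the retinoid list was not called (median 0.93 against 1.42 with all arrays, adjusted p = 0.0772), nor were Ier2 (1.15 ± 0.36, adjusted p = 0.0691) and Junb (1.38 ± 0.52, adjusted p = 0.122). With median centring 1 stress gene rose and 0 fell.

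Markers of other cell types were partly called between urothelium and detrusor. Of 7 pericyte genes, 4 fell, among them Kcnj8 (log2 -3.33 ± 0.53), Cspg4 (-2.96 ± 0.61) and Mcam (-3.01 ± 0.67), and Rgs5 rose (2.35 ± 0.55), with the same numbers over the list alone. For the pericyte genes, camera gave adjusted p = 0.034, and adjusted p = 0.509 with an estimated correlation. Of 10 neural and glial genes, Uchl1 (3.58 ± 0.53) and the ErbB receptor gene Erbb3 (3.35 ± 0.58) rose and Fabp7 (-2.94 ± 0.64) fell, or 2 and 3 over the list alone (list median -0.39, mean 0.09, adjusted p = 0.854). Msln rose (2.51 ± 0.61), 1 of 5 mesothelial genes, also 1 over the list alone (list adjusted p = 0.305). The endothelial list had 0 called members of 14 (median -0.54, adjusted p = 0.135), the macrophage list 0 of 15 (-0.79, adjusted p = 0.121) and the erythroid list 0 of 2 (0.52, adjusted p = 0.738). Array weights raised the count of called genes from 2145 to 3785, and it was 1172 without detrusor 3 and 1326 without urothelium 2. Without stroma 3 and urothelium 3 together it was 1884.

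Across the 3 layers, the limma F-test called 1951 genes. Against both other layers, 305 genes were enriched in detrusor, with Trdn (smaller of the 2 differences 6.55 log2 units), P2rx1 (6.23), Ckm (5.59), Rims1 (5.52), Myh8 (5.51) and Tenm2 (5.48) first. Trdn lies near the bottom of the scale in stroma and urothelium, and Myh8 in stroma and in urothelium 1 and 2, so this order depends on the pseudocount. Urothelium had 7 enriched genes, Cldn8 (4.20), Mpzl3 (3.46), Sytl2 (2.81), Gstm4 (2.71), Dcaf12l1 (2.57), Hsdl2 (2.35) and Nabp1 (2.27), the last named because the set is small. Stroma had 1, the secreted serine protease gene Htra1 (1.18), with mean log2 levels of 15.3 in stroma, 14.1 in detrusor and 13.1 in urothelium. Htra1 was not among the 9 genes enriched in stroma without stroma 3 and urothelium 3. The F-test called 1200 genes without detrusor 1, 1056 without detrusor 2, 813 without detrusor 3, 1244 without urothelium 1, 1200 without urothelium 2 and 3162 with array weights. Leaving out 1 array gave between 51 and 345 genes enriched in detrusor (134 without detrusor 1, 89 without detrusor 2, 51 without detrusor 3, 178 without stroma 3). It gave between 0 and 266 in urothelium (266 without stroma 3, 11 without stroma 2, 4 without detrusor 2, and 0 without detrusor 1, detrusor 3, stroma 1, urothelium 1 or urothelium 2). In stroma it gave between 0 and 12 (12 without stroma 3, 9 without stroma 2, 3 without urothelium 3, and 0 without any other).

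Between postnatal days 1 and 2, with layer as a covariate, limma called 2 genes. Eif2s3y, a gene of the Y chromosome, was higher on day 2 (log2 6.52 ± 0.33, SE, adjusted p = 2.58e-05), and Xist, the RNA that coats the inactive X chromosome, was lower (-7.91 ± 0.48, adjusted p = 8.21e-05). All 4 arrays of day 1 had Xist log2 levels from 15.6 to 16.4 and Eif2s3y levels from 5.82 to 5.98. All 5 arrays of day 2 had Xist levels from 6.62 to 8.95 and Eif2s3y levels from 11.9 to 12.9. The labels give the sex as unknown, so in these arrays the 2 ages also differ in sex-linked transcripts. Detrusor had more day 1 arrays than the other layers. Comparisons with detrusor are therefore partly mixed with day and with these transcripts. With the 2 called ones included, 727 genes had an unadjusted p under 0.05. The count of called genes was 4 without detrusor 3.

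**Figure D4:**
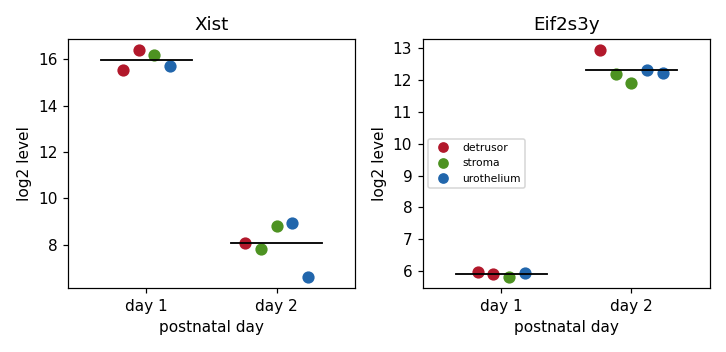
Log2 levels of Xist and Eif2s3y on each array by postnatal day, 1 point per array coloured by layer, with a line at the mean of the arrays of each day. The 4 day 1 arrays have Xist above 15 and Eif2s3y below 6, and the 5 day 2 arrays the reverse.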

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

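The tests of explanations in this part were all chosen after the results were seen. Signal differing between layers was also present in probe sets that entered no comparison of genes because the annotation gives them no symbol or several. Of 3486 such probe sets past the filter, limma called 66 between detrusor and stroma (29 higher and 37 lower in detrusor), 1 between urothelium and stroma (lower in urothelium) and 140 between urothelium and detrusor (71 higher and 69 lower in urothelium). They are given as counts only, and 586, 397 and 515 had an unadjusted p under 0.05. A test of whether the difference between days depends on the layer called 0 genes with limma, and 812 had an unadjusted p under 0.05. On simulated values that test recovered 0% of changes of 4 log2 units and 80% of changes of 8, so the count of 0 leaves smaller ones open. Groups of 3 arrays are too small for a test of single outlying arrays.

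Stroma 3 carried urothelial transcripts. Its fibroblast list median lay 2.40 log2 units above the mean of urothelium 1 and 2, and at 14.7 near stroma 2 (14.6). This argues against a wrongly labelled array of urothelium alone. Urothelium 3 also lay above urothelium 1 and 2 on that list (13.8 against 12.5 and 12.2). A wrongly labelled urothelium array with other tissue in it is therefore not excluded. Postnatal day does not account for the urothelial transcripts, since stroma 2 has the same day and lay 3.90 lower in the uroplakin list. Urothelial material in the captured stroma may be the source: of 248 genes at least 3 log2 units higher in urothelium 1 and 2 than in any detrusor array, 83.5% were over 1 log2 unit higher in stroma 3 than in stroma 2. Taking stroma 2 and the mean of urothelium 1 and 2 as the ends, the median share per gene was 36.6% (quartiles 23.6 and 51.4), and 9.56% for stroma 1. For 7 of the 248 genes stroma 2 lay above the urothelium end, and over the other 241 the median was 35.9%, with 13 genes above 100%, among them Krt8 (156.4%), Gata3 (120.9%) and Upk1b (106.6%). A single share of urothelial material therefore leaves some genes unaccounted for. That a real difference between individual animals adds to this stays open, since the labels name no animals.

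Urothelium 3 carried smooth muscle transcripts. Its uroplakin list median lay 6.08 log2 units above the detrusor mean, which argues against a mislabelled detrusor array, and its smooth muscle list median lay 3.48 above urothelium 1, an array of the same postnatal day. Of 190 genes at least 3 log2 units higher in detrusor than in urothelium 1 and 2, 85.8% were over 1 log2 unit higher in urothelium 3, so detrusor material in the captured urothelium may be the source. The median share was 18.9% (quartiles 10.4 and 29.1), but Actg2 stood at 94.8% and Trdn at 0.0708%. A single share of detrusor material therefore leaves some genes unaccounted for, and smooth muscle of another kind was not tested.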

How the results depend on the processing

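The alternatives below were planned except those that leave out several arrays, which were chosen after the values were seen. Which named genes to follow (those called, and Actg2) was narrowed after results were seen. Over their planned settings other than leaving out an array, direction and call held 1328 times and direction alone 128 times. With 1 array left out these numbers were 964 and 233, and no named gene reversed. The urothelium and stroma count, 30 genes, gave 93 with quantile normalization, 223 with median centring, 13 and 304 with the pseudocount at the 5th percentile and the median, 10 without a filter, 139 with the filter at the 75th percentile, 116 with the mean over probe sets, 0 without the variance trend, 11 with array weights, 10 with postnatal day as a covariate, 0 with only the 6 arrays compared, 440 without stroma 3 and urothelium 3 and 639 also without stroma 1, where the lone stroma array is assumed to vary like the other groups. Leaving out 1 array gave 0 to 528. All 30 genes were called again among the 440. In the same order of settings, the 7 genes enriched in urothelium became 31, 150, 2, 139, 1, 47, 29, 0 (no trend), 1 (array weights), 2 (day), 180 and 309, with 4 for every probe set on its own and 0 to 266 with 1 array left out. The 1 gene enriched in stroma became 3 (quantile), 0 (median centring), 16 (pseudocount at the median), 5 (75th percentile), 7 (mean over probe sets), 2 (every probe set), 0 (no trend), 9 and 67 (arrays left out together), and 0 to 12 with 1 array left out. The other counts stayed within 1.5 times of their value except as follows. The detrusor and stroma count was 428 without stroma 3 and urothelium 3, of which 355 were among the 763, and 105 to 851 with 1 array left out. The urothelium and detrusor count was 3785 with array weights and 1172 to 2435 with 1 array left out. The F-test gave 3162 with array weights and 813 to 2180 with 1 array left out, and the genes enriched in detrusor 51 to 345. The day count was 5 with every probe set on its own and 2 to 4 with 1 array left out. Of the 29 list calls, 0 held with an estimated correlation (lowest adjusted p = 0.381) and fry called 13 of them by direction. Between urothelium and stroma, fry called only the fibroblast and matrix list (adjusted p = 0.0328). Between urothelium and detrusor, fry did not call the mesenchymal transcription factor (adjusted p = 0.052), pericyte (0.085) and skeletal muscle (0.143) lists that camera called. Over all 57 tests fry called 15, and camera with 1 array left out 23 to 31. The gene list tests were not run on every probe set. Fewer arrays and fewer genes tested change the adjustment by construction, and the other causes were not tested. Without detection calls the lowest signals cannot be told from background. No paired analysis was possible because the replicate numbers were given in accession order and the labels tie no samples of different layers to 1 animal. The titles carry numbers that all differ. Those of stroma 3, urothelium 1 and urothelium 3 are near each other, and stroma 3 correlated with these 2 at 0.904 and 0.890, but the labels do not say what the numbers mark.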

Other observations

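With stroma 3 and urothelium 3 left out, a choice made after the values were seen, urothelium and stroma separated on more of the fixed lists. These arrays were picked for their urothelial and smooth muscle transcripts. Larger differences on the epithelial and contractile lists follow from that choice and are no separate evidence. The matrix list is not free of the choice either, with a median of 13.8 in urothelium 3 against 12.5 and 12.2 in urothelium 1 and 2. Of the fibroblast and matrix genes 21 of 27 were then lower in urothelium (median -2.59), of the mesenchymal transcription factors 5 of 23 and of the contractile genes 4 of 26, while 5 of 11 uroplakin genes, 5 of 25 keratin and junction genes and 3 of 14 epithelial transcription factors were higher. Psca (log2 5.99 ± 0.62, SE), the desmosomal genes Dsg2 (4.06 ± 0.44) and Dsc2 (4.45 ± 0.76), Cldn7 (3.95 ± 0.52) and Tfap2c (5.12 ± 0.92) rose, and Tcf21 (-3.35 ± 0.55) and Gli2 (-2.08 ± 0.36) fell. Of the genes then enriched, named after they were seen, the 180 in urothelium began with Atp10b, the sodium channel subunit gene Scnn1g, Hsd17b2, Prom2, Syt16 and Psca, with smaller differences from 6.36 down to 5.89, and Shh stood at 5.80. The 9 in stroma were Rpl39l, 3110045C21Rik, the macrophage gene Mpeg1, Itga4, Plac1, Cbln2, Gas7, Tusc1 and Mmp2. With an estimated correlation 0 of 27 list calls held in this setting either.

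The stroma arrays also differed from each other in markers of further cell types, given here after their levels were seen. Wt1 and Bnc1, both in the mesothelial list, had log2 levels of 12.5 and 11.5 in stroma 2, 7.87 and 8.57 in stroma 1, and 10.5 and 8.18 in stroma 3. The median of that list was 8.42, 9.74 and 10.2 in stroma 1, 2 and 3, and 10.2 in urothelium 1. The macrophage list median was 11.2 in stroma 1, 8.83 in stroma 2 and 10.02 in stroma 3, and the endothelial list median was 12.1, 11.3 and 11.4. Ptch1 stood at 15.4, 14.7 and 14.9 in stroma, at 12.7 to 13.0 in detrusor and at 13.6 to 14.2 in urothelium, while Shh stood at 10.5, 8.70 and 14.6 in stroma and ranged from 5.52 to 6.40 in detrusor and from 15.2 to 15.6 in urothelium.

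The tests in the paragraphs that follow were all chosen after the results were seen. Some striated muscle transcripts were high in detrusor, 3 of 9 tested skeletal muscle genes being called against stroma. Over the 12 skeletal muscle list genes, detrusor 1 had a median 4.03 log2 units above the stroma mean, with 9 genes over 1 unit higher, so skeletal fibres in that capture are a candidate source for that array. In detrusor 2 and 3 the median was -0.90, with 4 genes over 1 unit higher and 7 below 0, among them Myl1 (-2.61) and Mylpf (-0.86), which skeletal fibres would bring, and this argues against skeletal fibres as the source there. Expression in smooth muscle itself stays open for Ckm, Tnnt3, Myh8 and Acta1. All 4 were over 1 log2 unit higher in urothelium 3 than in urothelium 1 and 2, but so were 85.8% of all genes far higher in detrusor, so this does not decide it.

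The sex of the animals may account for the genes differing between postnatal days, since 2 of the 2 called genes were among the sex-linked genes fixed in advance. The Y genes Kdm5d (6.65 to 8.35 on day 1, 7.38 to 10.3 on day 2) and Uty (6.36 to 7.49 and 7.03 to 8.48) overlapped between days. Age of the animals cannot be told apart from sex in these arrays, with 0 called genes outside that set. Among 27 splits that keep each layer's number of day 1 and day 2 arrays, 1, the real one, gave as many genes. The highest other gave 1. Xist and Eif2s3y divided the arrays in the same way, so a split across that division loses calls. The splits therefore restate that day and sex-linked transcripts fall together here. They do not exclude chance for a difference between ages.

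Regrouping the arrays bears on the other counts. Groups of 3 arrays allow 10 splits, too few for a share under 0.05. The real value was 763 and the highest other 0 for detrusor and stroma, 30 and 4 for urothelium and stroma, and 2145 and 0 for urothelium and detrusor, and in each pair 1 split, the real one, reached the real value. Over 100 splits of the 9 arrays into 3 groups, the real one and others drawn at random from all possible ones, 1 split, the real one, reached the F-test count (1951, highest other 1057). The same held for the genes enriched in detrusor (305 against 242). Splits that break up the detrusor arrays put layer differences into the spread within groups, which lowers their counts. The highest other values came from splits that keep the detrusor arrays together. Not every split of that kind was drawn, so higher values among the rest are not excluded. Chance is thus excluded at most for detrusor set apart from the other arrays. For the list calls 3 splits, the real one included, gave as many as the real 29, a share under 0.05. Regrouped arrays thus reached this count and passed it, so chance is not excluded for the list calls. The other splits gave 5 to 31 calls with a median of 17, so a call at the preset correlation is common in regrouped arrays. For the 7 genes enriched in urothelium and the 1 in stroma, 6 splits each gave as many in some group, up to 242, so chance cannot be excluded. The 5 splits other than the real one all keep the 3 detrusor arrays together, so this comparison says little about either layer.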
